A study of Homo sapiens with 6 samples.

How the data were processed

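The series holds 6 RNA-seq libraries of HCT116, an established human line from a poorly differentiated colon carcinoma, 3 carrying a scrambled control shRNA (shControl) and 3 carrying an shRNA against TRIM21 (shTRIM21). Both shRNAs were delivered by lentivirus. Per the labels' protocols, puromycin at 5 µg/ml was added 36 h after infection and kept for 2 to 3 weeks, and the cells are labelled day 21. Total RNA was extracted with Trizol and depleted of ribosomal RNA (rRNA), and libraries were made with a low-input kit. The labels call the libraries biological replicates and do not say that they came from separate cultures, so the p-values given here measure only the spread between these samples, which may be technical.

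The authors deposited raw counts per gene symbol for each library, whole numbers with no normalization. Per the submitters' processing notes, TopHat2 2.1.1, edgeR 3.38.1 and limma 3.52.2 were used with the hg38 genome. The counting tool, its annotation, its strand setting and its treatment of reads with several positions are not given in the sources used here. The tables hold 28278 symbols, of which 9276 were at 0 in all libraries. Copies of the rRNA genes carry identical counts, so a read was counted at each copy there. MALAT1 and its antisense partner TALAM1 held 50395 and 48505 counts in shControl replicate 1, so genes that overlap on opposite strands could not be told apart. CANX, RPL7A, ZYX, TJP1 and NDUFS1, which nearly every cell line transcribes, were listed at 0 in all libraries, so a 0 in these tables is not read as absence. Mitochondrial genes were not analysed here.

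Counts were tested with edgeR 4.0.16 (R 4.3.3) after its default filter on low counts, which left 14002 genes, and TMM scaling. The quasi-likelihood test compared shTRIM21 with shControl with no other term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts relative to the library size scaled by TMM, as mean ± SD over 3 libraries per group, and levels quoted over all 6 libraries are CPM of the total count. Gene lists were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members. Of 35 lists, 30 met that minimum, and p-values were adjusted by Benjamini-Hochberg over them. Gene positions come from GENCODE release 29 (GRCh38), which matched 26218 of the symbols.

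The groups, the tests, the lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule named TRIM21, then the 12 genes with the largest increase and the 12 with the largest decrease among ordinary symbols past the threshold, with at least 5 CPM in the higher group and no overlap between the groups. It then named up to 4 members of each list described and any member that went the other way. Some genes that met the rule are not reported here. Alternatives covered the scaling, the filter, DESeq2 1.42.0, limma-voom, the 20 most abundant genes left out, each library left out, the replicate number as a block, a test against a fold of 1.5, and other gene set tests. Added after the data were seen were fits without the rRNA genes, without replicate 3 of both groups, with an offset for GC content and length, and without genes that hold either of 2 sequences of 7 bases (7-mers) in the 3′ UTR.

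The 7-mer scan used Python 3.11.15 and numpy 2.4.6. It covered 9206 genes with an annotated 3′ UTR and a mean log2 CPM of at least 3, and 15919 7-mers found in at least 100 of them. Fold changes, limited to 1.5 on the log2 scale, were regressed on the presence of each 7-mer in the longest annotated 3′ UTR, with the length and GC content of the UTR and of the transcript and the expression level as covariates. Each score is the shift divided by its SE, and it was set against the most extreme score of any 7-mer in 200 permutations of the fold changes among genes of like UTR length.

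Library totals ran from 22656160 to 27123657 counts. In 10 simulated sets of counts for the 14002 genes, drawn from these libraries' means, sizes and spread with 200 changed genes each, the test recovered 32.8% of genes changed 1.25-fold, 66.2% of those changed 1.5-fold, 85.2% of those changed 2-fold and 96.6% of those changed 3-fold. Of its calls there, 8.18% were false. The changed genes were drawn only from tested genes above a minimum mean CPM, so recovery at the lowest levels was not measured. With the mitosis list lowered by 0.3 on the log2 scale in simulated counts, camera called that list and 0 others. Genes were drawn independently of each other there, so this does not check camera's preset correlation. In permuted fold changes of the 9206 scanned genes, a 7-mer given a shift of -0.05 ranked first on the lower side.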

Results

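RNA was profiled in HCT116 colon carcinoma cells that stably carried either a scrambled control shRNA or an shRNA against TRIM21, with 3 libraries per group. The shControl libraries held 25078521, 24646400 and 27123657 counts for replicates 1 to 3, and the shTRIM21 libraries 25842818, 22656160 and 25220745. Genes of rRNA took 11.5% ± 4.26 (SD, n = 3) of the counts in shControl and 12.8% ± 2.91 (SD, n = 3) in shTRIM21, a difference smaller than the spread within either group. These shares overstate the share of reads, since a read was counted at each copy of an rRNA gene. The lowest rRNA share of each group was in replicate 3, at 6.69% in shControl and 9.55% in shTRIM21. The biological coefficient of variation was 10.7%, and the first principal component, with 33.0% of the variance, separated the groups. The second, with 23.4%, followed the replicate number in both groups. Its scores were 12.2, 5.87 and -31.8 for shControl replicates 1 to 3 and 22.9, 5.49 and -14.7 for shTRIM21. Replicate 3 scored lowest in each group and stood clearly apart from the other replicates only in shControl. The series makes 1 comparison, which asks how gene expression differs between shTRIM21 and control cells.

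TRIM21, an E3 ubiquitin ligase and cytosolic antibody receptor, fell in the shTRIM21 cells, from 13.1 ± 2.33 CPM to 7.90 ± 1.10 CPM (SD, n = 3 per group). The gene lies on the minus strand of chromosome 11 at 4384897 to 4393696 (GRCh38, ENSG00000132109). Its raw counts were 288, 286 and 443 in shControl and 225, 182 and 173 in shTRIM21, so that every shTRIM21 library lay below every shControl library. The log2 fold change was -0.73 (SE 0.17), with an adjusted p of 0.0124 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, leaving 0.603 of the control level. The call was lost without shTRIM21 replicate 3, at -0.62 and an adjusted p of 0.0734, and without replicate 3 of both groups, at -0.45 and an adjusted p of 0.114, while edgeR, DESeq2 and limma-voom fits gave adjusted p from 0.000849 to 0.114 over all alternatives.

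**Figure D1:**
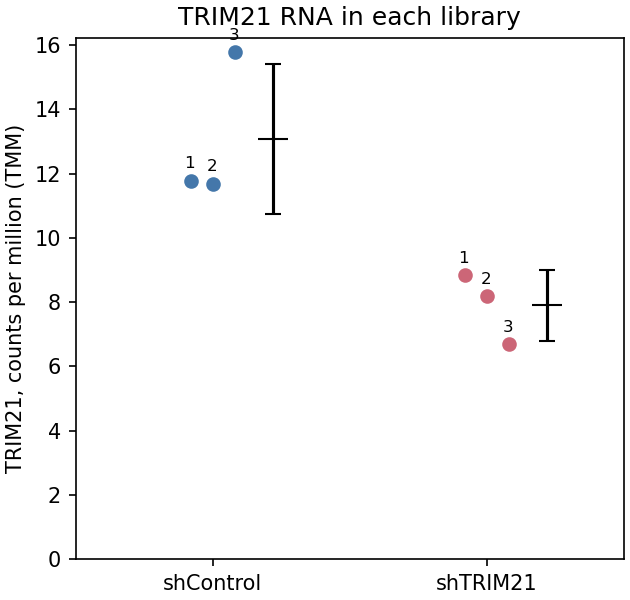
TRIM21 level in each library in TMM-scaled CPM, with the replicate number above each point, and the mean and SD of each group (n = 3) beside the points. The group means are 13.1 CPM in shControl and 7.90 CPM in shTRIM21, and the 3 shTRIM21 points lie below the 3 shControl points.

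In the shTRIM21 cells 620 genes rose and 652 fell among the 14002 tested, and 59 of those that rose and 31 of those that fell changed at least 2-fold. Among changed genes with at least 5 CPM in the higher group, ordinary symbols and no overlap between the groups, the largest increases were in AMOTL1, an angiomotin-family protein of cell junctions, which went from 1.55 ± 0.27 to 6.63 ± 1.57 CPM, and in IL13RA2, a decoy receptor for interleukin 13, which went from 9.25 ± 0.812 to 30.1 ± 0.957 CPM (SD, n = 3 per group). HMOX1, which breaks down heme, rose from 33.2 ± 6.13 to 84.1 ± 8.73 CPM, and S100A2, a calcium-binding protein, from 133 ± 7.03 to 291 ± 1.77 CPM. HAS2, the hyaluronan synthase, fell from 45.9 ± 5.90 to 15.0 ± 0.941 CPM, and AGPAT4, an acyltransferase of phospholipid synthesis, from 9.22 ± 0.424 to 2.93 ± 1.24 CPM. PLAU, the urokinase plasminogen activator, fell from 51.2 ± 0.387 to 24.9 ± 2.90 CPM.

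Under the same limits, the other genes with the largest increases were CD163L1 (log2 fold change 1.45, SE 0.24), SH3TC2 (1.38, SE 0.16), GEM (1.31, SE 0.07), PARM1 (1.25, SE 0.25), ALG5 (1.22, SE 0.14), H2BC9 (1.19, SE 0.29), AHNAK2 (1.11, SE 0.14) and ARL2BP (1.10, SE 0.07). The other genes with the largest decreases were FAM120C (-1.36, SE 0.29), TIMP2 (-1.17, SE 0.19), CADPS2 (-1.09, SE 0.25), CNTF (-1.07, SE 0.26), SLC16A10 (-1.02, SE 0.11), C10orf55 (-0.98, SE 0.19), MINAR1 (-0.95, SE 0.27), ARHGAP29 (-0.95, SE 0.10) and ACSF2 (-0.94, SE 0.22). C10orf55 overlaps PLAU on the opposite strand of chromosome 10, and their reads could not be told apart. The 3′ UTRs of HAS2, FAM120C, TIMP2, CNTF, SLC16A10 and ARHGAP29 hold the 7-mer AGTGGAA, and those of AMOTL1, ALG5 and ARL2BP hold GTGTCAC, the 7-mers that went furthest with lower and with higher fold changes across the 9206 genes scanned. AGTGGAA also occurs in PARM1, and GTGTCAC in AGPAT4, which moved the other way. Among scanned genes AGTGGAA was in 44.1% of 581 that fell, 16.2% of 519 that rose and 18.9% of 8106 that did not pass, and GTGTCAC in 10.3%, 24.1% and 11.2%, shares not matched for UTR length and not a test, since both 7-mers were picked from the same fold changes. In edgeR's test H2BC9 lost its call without shControl replicate 1 (adjusted p = 0.0622) or shTRIM21 replicate 1 (0.0589), CADPS2 without shControl replicate 2 (0.0662) or shTRIM21 replicate 2 (0.0616), CNTF without shControl replicate 1 (0.0809) and ACSF2 without shTRIM21 replicate 3 (0.0635) or replicate 3 of both groups (0.0935). MINAR1 lost it without shControl replicate 1 (0.0784), shControl replicate 3 (0.0948), shTRIM21 replicate 2 (0.0778), shTRIM21 replicate 3 (0.14) or replicate 3 of both groups (0.233, log2 fold change -0.52).

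**Figure D2:**
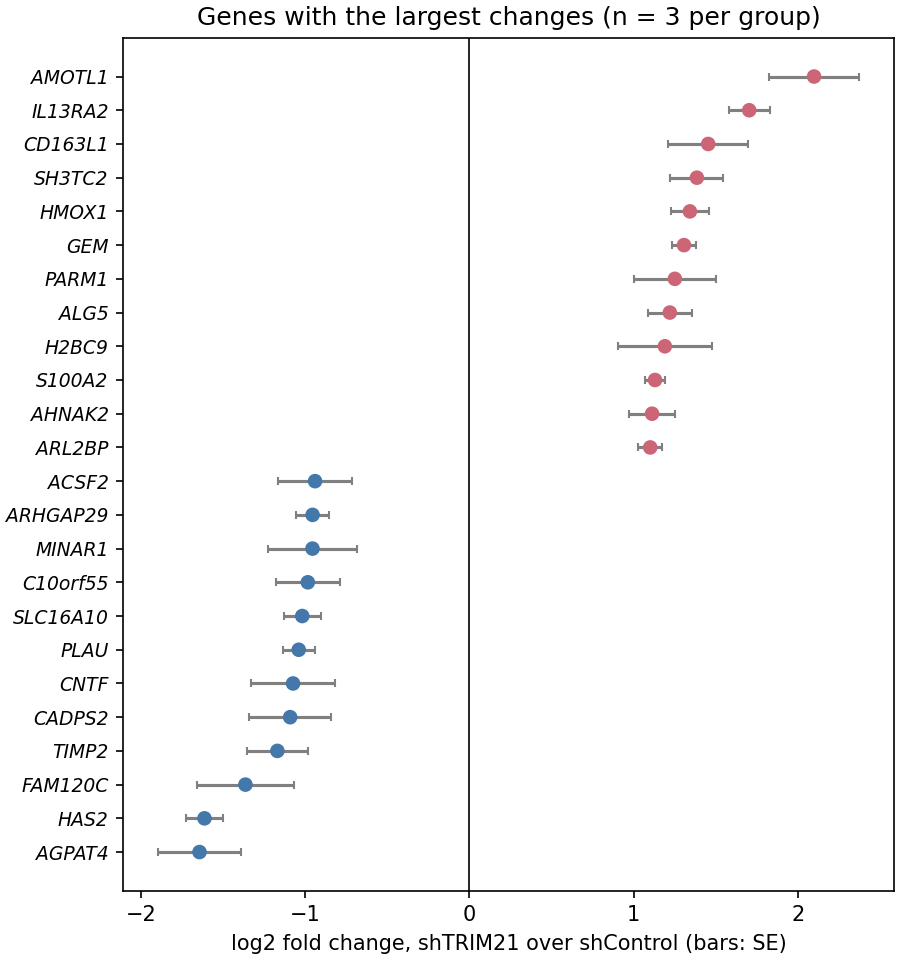
Log2 fold change of shTRIM21 over shControl, with the SE as bars, for the 12 genes with the largest increase (red) and the 12 with the largest decrease (blue) among changed genes with at least 5 CPM in the higher group, ordinary symbols and no overlap between the groups, 3 libraries per group. The largest increase shown is that of AMOTL1 and the largest decrease that of AGPAT4 (-1.64).

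The 1272 changed genes were 9.08% of those tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3188 had an unadjusted p under 0.05. Their median absolute log2 fold change was 0.39. The groups did not overlap for 28.1% of all tested genes, where chance gives 10% for 3 against 3. Calls numbered 683, 801 and 1737 without shControl replicates 1, 2 and 3, 694, 673 and 602 without shTRIM21 replicates 1, 2 and 3, and 1459 without replicate 3 of both groups. The genes changed at least 2-fold numbered 55, 65 and 134 without shControl replicates 1, 2 and 3, 66, 60 and 55 without shTRIM21 replicates 1, 2 and 3, and 145 without replicate 3 of both groups. An offset for GC content and length gave 1909 calls, leaving out the genes with either 7-mer gave 648 of 10832 tested with 47 changed at least 2-fold, and a test against a fold of 1.5 gave 21 in place of 90.

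Genes of the G2 phase and mitosis lay lower than other genes as a list in the shTRIM21 cells by camera with a preset correlation (adjusted p = 2.14e-09), a call lost with an estimated correlation (0.104). Of 30 tested members 15 fell, 0 rose and 15 did not pass (18 fell and 0 rose adjusted over the list alone), 29 had a negative fold change, and the median log2 fold change was -0.22. CENPE, a kinetochore motor, fell by 0.53 (SE 0.07) on the log2 scale, and the proliferation marker MKI67 fell by 0.44 (SE 0.07), from 1425 ± 57.4 to 1053 ± 25.7 CPM (SD, n = 3 per group). DLGAP5 and KIF11, both of the mitotic spindle, fell by 0.43 (SE 0.08) and 0.40 (SE 0.07). MKI67 holds AGTGGAA in its 3′ UTR, and the list's median was -0.23 without the genes that hold either 7-mer.

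Autophagy and lysosome genes lay higher than other genes as a list by camera with a preset correlation (adjusted p = 5.69e-06), as did targets of the hypoxia-inducible factors (HIF; 4.92e-05), and both calls were lost with an estimated correlation (0.104 each). Of 32 autophagy and lysosome genes 11 rose, 0 fell and 21 did not pass (18 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 0.25. The lysosomal hydrolase CTSB, with AGTGGAA in its 3′ UTR, rose by 0.50 (SE 0.07), the cholesterol transporter NPC1 by 0.48 (SE 0.10), and the protease CTSD by 0.50 (SE 0.12), a call of edgeR's test that was lost without shTRIM21 replicate 1 (adjusted p = 0.0613) or 3 (0.0541).

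Of 25 HIF targets 9 rose, 0 fell and 16 did not pass (13 rose and 1 fell adjusted over the list alone), with a median of 0.29. NDRG1 rose by 1.00 (SE 0.10), the transcription factor BHLHE40 by 0.73 (SE 0.06) and ANGPTL4 by 0.66 (SE 0.13). DDIT4, an inhibitor of mTORC1 signalling, rose by 1.41 (SE 0.32) from 1.86 ± 0.728 CPM (SD, n = 3), a call of edgeR's test lost without shTRIM21 replicate 2 (adjusted p = 0.0677).

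Antioxidant genes controlled by NRF2 also lay higher as a list by camera with a preset correlation (adjusted p = 0.00032), a call lost with an estimated correlation (0.114), with 8 of 23 higher, 1 lower and 14 that did not pass (11 higher and 1 lower adjusted over the list alone) and a median of 0.24. Besides HMOX1 (1.34, SE 0.11), the ferritin light chain FTL rose by 0.56 (SE 0.08), from 928 ± 72.5 to 1370 ± 99.1 CPM (SD, n = 3 per group), and SRXN1, which holds GTGTCAC in its 3′ UTR, rose by 0.48 (SE 0.06). GSR, the glutathione reductase, went the other way (-0.50, SE 0.07) and holds AGTGGAA in its 3′ UTR. With an offset for GC content and length the median was 0.14 and the adjusted p 0.0012.

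Of 27 p53 targets 6 rose and 0 fell, by the test over all genes and adjusted over the list alone, and 21 did not pass, with a median of 0.12. CDKN1A, the p21 cell cycle inhibitor, rose from 84.3 ± 4.13 to 116 ± 3.33 CPM (SD, n = 3 per group), TP53I3 rose by 0.94 (SE 0.20), and BTG2, with AGTGGAA in its 3′ UTR, by 0.55 (SE 0.09). Camera gave an adjusted p = 0.00213, the adjusted p = 0.104 with an estimated correlation, and an adjusted p of 0.00223 with the offset for GC content and length, where the median was 0.12. Glycolysis genes had 7 of 21 members higher, 2 lower and 12 that did not pass (10 higher and 2 lower adjusted over the list alone). The neuronal-type enolase ENO2, with GTGTCAC in its 3′ UTR, rose by 0.67 (SE 0.07), while the lactate transporter SLC16A1 fell by 0.41 (SE 0.07). Their median of 0.15 had an adjusted p = 0.00658 by camera, and the adjusted p = 0.329 with an estimated correlation. With the offset for GC content and length the median was 0.05 and the adjusted p 0.0511, and without replicate 3 of both groups they were 0.12 and 0.085, so each of these fits ended the call.

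Nuclear genes of the respiratory chain and genes of ribosomal proteins lay higher as lists by camera with a preset correlation (adjusted p = 0.000106 and 2.16e-06), calls lost with an estimated correlation (0.104 and 0.163). Of 43 respiratory chain genes 8 rose, 1 fell and 34 did not pass (12 rose and 1 fell adjusted over the list alone), with a median of 0.17. UQCRC2, a core subunit of complex III, went down (-0.46, SE 0.08). Of 63 ribosomal protein genes 4 rose, 0 fell and 59 did not pass, with the same counts adjusted over the list alone, yet 61 had a positive fold change and the median was 0.12. With the offset for GC content and length the medians were 0.08 and 0.04, with adjusted p of 0.0103 and 0.0167 by camera.

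**Figure D3:**
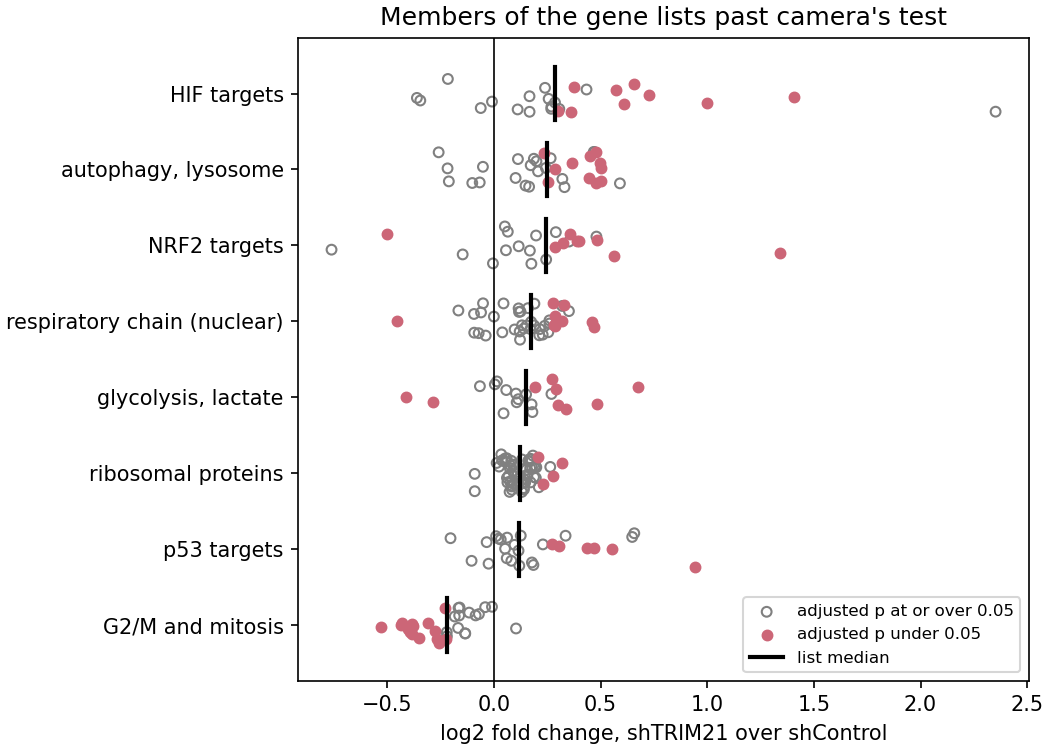
Log2 fold change of shTRIM21 over shControl for each tested member of the 8 gene lists past camera's test with a preset correlation, as filled points where the member itself passed edgeR's test and open points where it did not, with the list median as a black bar. The mitosis list has a median of -0.22, and the other lists have medians from 0.12 to 0.29.

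The interferon-stimulated genes did not pass as a list (camera adjusted p = 0.0844), nor did the MHC class I genes (0.0824), with medians of 0.10 and 0.14. Both lists were among the 14 that passed fry, which does not compare a list with other genes (fry adjusted p = 0.0124 and 0.0364). Of 32 interferon-stimulated genes 2 rose and 1 fell (5 rose and 1 fell adjusted over the list alone). Of 18 NF-kB targets 4 rose and 0 fell, by the test over all genes and adjusted over the list alone (camera adjusted p = 0.736). They included SOD2, with GTGTCAC in its 3′ UTR, which rose by 0.44 (SE 0.06), and ICAM1, with AGTGGAA, which rose by 0.37 (SE 0.08). Among DNA replication genes 4 of 38 rose and 1 fell (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.432). MCM6, a helicase subunit with GTGTCAC in its 3′ UTR, rose by 0.57 (SE 0.07), and CCNE1, cyclin E1, by 0.44 (SE 0.09).

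Single genes changed inside other lists that did not pass camera's test. CCND1, cyclin D1, fell from 219 ± 1.98 to 130 ± 5.77 CPM (SD, n = 3 per group). VIM, the mesenchymal intermediate filament, with GTGTCAC in its 3′ UTR, rose from 5.55 ± 0.346 to 11.4 ± 1.02 CPM. Of 17 mesenchymal genes 4 rose and 1 fell, over all genes and adjusted over the list alone. As a list the mesenchymal genes did not pass camera (adjusted p = 0.313) but passed fry (adjusted p = 0.00468). The protease inhibitor TIMP1 rose by 0.66 (SE 0.09). CD68, a lysosomal glycoprotein and macrophage marker from a leukocyte list too short for camera, rose from 436 ± 41.2 to 648 ± 36.0 CPM (SD, n = 3 per group). Among relatives and partners of TRIM21, TRIM26, with GTGTCAC in its 3′ UTR, rose by 0.64 (SE 0.09), and RO60, the RNA-binding Ro autoantigen, with AGTGGAA, fell by 0.36 (SE 0.06).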

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

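The fits without replicate 3 of both groups, without rRNA genes, with the offset for GC content and length, and without genes that hold either 7-mer were chosen only after the result was seen. The genes changed numbered 602 to 1737 with 1 library left out, 1909 with the GC and length offset and 648 without genes with either 7-mer, where 10832 genes were tested, against 1272. Those changed at least 2-fold numbered 55 to 134 with 1 library left out, 145 without replicate 3 of both groups, 47 without genes with either 7-mer and 21 with glmTreat against a 1.5-fold change, a stricter question, against 90. TRIM21 ranged from -0.82 to -0.56 with 1 library left out, and lost its call without shTRIM21 replicate 3 (-0.62) and without replicate 3 of both groups (-0.45). Of the lists, camera with an estimated correlation called 0 and fry, which does not compare a list with other genes, called 14, against 8. The cause was not tested where fewer libraries or genes do not account for it. No other scaling, filter or tool moved these 4 results past 1.5 times or ended the TRIM21 call. The other 105 named genes kept their direction under every alternative, and 59 of them also kept their call. Same-numbered libraries deviated from their group means with correlations of 0.096, -0.012 and 0.091, so that numbers 1 and 3 correlated best with their own number and number 2 did not, and the main fit is unpaired. With the replicate number as a block, the count of genes changed was 1699, with 118 changed at least 2-fold, and TRIM21 (-0.72) and 8 lists were called. With 22656160 to 27123657 counts per library, changes of 1.25-fold were recovered for 32.8% of simulated genes, which left out those with the lowest mean CPM.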

Other observations

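The tests of base composition, of the control shRNA, and of single libraries, both tests of the epithelial genes, and the offset for GC content and length were chosen only after the result was seen.

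Several genes of epithelial identity were near the floor in all 6 libraries. CDH1, the epithelial cadherin, averaged 4.11 ± 0.647 CPM (SD, n = 6), KRT19 1.17 ± 0.202 CPM and CDH17, the intestinal cadherin, 0.795 ± 0.386 CPM. Other epithelial genes were well above that, with DSG2 at 269 ± 23.9 CPM, KRT18 at 74.5 ± 5.05 CPM, ESRP2 at 46.9 ± 1.52 CPM and EPCAM at 18.8 ± 1.49 CPM. Among intestinal genes VIL1, the microvillus protein villin, averaged 32.7 ± 1.99 CPM, CA2 19.0 ± 2.69 CPM and the intestinal transcription factor CDX2 8.96 ± 1.45 CPM. Most of that list was near the floor, with only 4 of 37 members at 5 CPM or more. Its median was 0.0406 CPM, and 13 members were at 0 in all libraries. The lists of fibroblast, endothelial, leukocyte and hepatocyte markers held fewer than 5 tested genes each. In them CD68 at 541 ± 119 CPM, TF at 18.2 ± 5.07 CPM and ESAM at 1.58 ± 0.857 CPM were the only ones above 1 CPM.

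Genes whose 3′ UTR holds AGTGGAA were lower in shTRIM21 (mean log2 shift -0.0478, SE 0.00558, 1871 genes), and genes with GTGTCAC were higher (0.0897, SE 0.00672, 1092 genes). Their scores were the most extreme on their sides of 15919 7-mers (permutation p = 0.005 each, the smallest that 200 permutations can give). On the lower side 3 7-mers passed the permutations at 0.05, all overlapping AGTGGAA, and on the higher side 5, of which GGAGAAC (score 5.31, p = 0.01, 1266 genes) does not overlap GTGTCAC and was not tested further. Relative to the mean of all libraries, the AGTGGAA shift lay between 0.0194 and 0.0287 in the 3 shControl libraries and between -0.0247 and -0.0225 in the 3 shTRIM21 libraries. For GTGTCAC it lay between -0.0475 and -0.0387 in shControl and between 0.0402 and 0.0471 in shTRIM21. Both 7-mers were picked from the group difference in these same libraries, so opposite signs of the group averages were fixed in advance. The values show only how alike the libraries of a group were. Scanned genes are not independent replicates.

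These shared 7-mers may come from microRNA-like activity, in which an shRNA lowers transcripts that pair with the start of its guide strand. The prediction for the TRIM21 shRNA, that the top 7-mer on the lower side would pass the permutations and occur in the TRIM21 transcript, was met by AGTGGAA (score -8.57), which lies in its coding sequence on chromosome 11 at 4388519 to 4388525 and at 4389681 to 4389687 (GRCh38, minus strand), although 10.8% of the tested 7-mers occur in that transcript. For base composition, 7-mers of the same bases were compared, apart from those that share 6 bases in a row with the top one. None scored beyond -2.67 on the lower side or 3.68 on the higher side. That they scored less was fixed by the choice of the top 7-mers, so only the margin counts. All scores were already adjusted for GC content, so the margin argues only against base composition beyond GC content, on both sides. Whether the control shRNA accounts for GTGTCAC (score 13.4), which does not occur in the TRIM21 transcript, cannot be told apart from another effect of the TRIM21 shRNA, because neither shRNA's sequence is given in the sources used here. An effect of lower TRIM21 itself stays open for all changed genes. The mitosis, autophagy and lysosome, and HIF lists kept medians of -0.23, 0.24 and 0.29 without the genes that hold either 7-mer. That fit cannot decide the cause of these shifts. It kept genes that hold only other 7-mers past the permutations, and it cannot remove indirect effects of an shRNA.

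Fold changes also followed GC content and length, with Spearman correlations across 11690 genes of 0.27 with GC content and -0.25 with transcript length. With an offset for both, the mitosis median was -0.25 against -0.22, the autophagy and lysosome median 0.20 against 0.25, and the HIF median 0.26 against 0.29, all still past camera's threshold with the preset correlation, so a GC and length bias is argued against as their whole cause, although without the offset these calls were lost with an estimated correlation (adjusted p = 0.104 each). For the ribosomal proteins (0.0437 against 0.12) and the respiratory chain (0.0810 against 0.17) the median fell to less than 1/2 of its size, so such a bias is a candidate explanation for much of those small shifts, and a coordinated change of short GC-rich genes stays open.

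For the low epithelial genes, loss of reads in the authors' counting cannot be told apart from low transcript levels. Only 11.1% of the 18 members below 5 CPM were at 0 in all libraries. Among 64 ribosomal protein genes, with a median of 453 CPM, RPL21 had 3.79 ± 1.20 CPM (SD, n = 6). RPL21 was chosen after its values were seen, and it was the only 1 of them below 5 CPM and not at 0. A value above 0 therefore does not exclude loss, but this rests on 1 gene outside the epithelial list. Whether these cells could be another line than the labels give cannot be told apart from a variant of HCT116 with little of these transcripts, because no reference profile was used here and the 18 of 32 low members do not decide it. No biological explanation was tested.

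Other splits of the 6 libraries into 3 and 3 give 10 splits, too few for a share under 0.05. For the genes changed 1 of the 10 splits, the real one, reached 1272, with 0 as the highest other, for those changed at least 2-fold 1 split reached 90, with 0 as the highest other, and for the lists 1 split reached 8, with 3 as the highest other.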
